A study of Mus musculus with 8 samples.

How the data were processed

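RNA was measured by sequencing in bulk mouse retina from 4 control samples (Phb2 flox/flox) and 4 rod_Phb2_KO samples (Phb2 flox/flox with RHO-cre), grouped by the genotype in the labels. A floxed gene carries recombination sites that let the cre enzyme remove the part between them, and RHO-cre places cre under control of the rhodopsin gene, which is active in rods. The control genotype lists no cre, so cre itself and loss of Phb2 were not separated by this design. Per the labels, RNA was extracted with TRIzol from 1 µg inputs. The protocol field of the samples names an NEBNext Ultra kit and the series' design text an Illumina TruSeq kit, and the disagreement was not resolved. Strand was not stated, so reads of overlapping or antisense genes, such as Fgf2 and Nudt6, could not be told apart.

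The deposited table held 1 column of signal per library, which the authors' file headers call counts. The values were not whole numbers and included fractions near 0 in the controls and knockout 4, so they were read as normalised read counts whose scaling is not given in the sources used here. Of the values above 0, 0% were whole to within 1e-06, so reads could not be recovered and the depth of each library is unknown. No counting interval or detection limit was computed for that reason. Per the submitters' processing notes, the tools were Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq 1.18.0, with genome build mm9. Each column name gave the group of a library, and the column numbers were used only as names (control 1 to 4 and knockout 1 to 4).

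The authors' deposited table also held a log2 fold change, a p-value and a q-value for each gene, knockout over control. It listed 778 genes, and the smallest absolute log2 fold change in the authors' deposited table was 1.00 and the largest q-value 0.0495. Its p-values and q-values implied 17910 tested genes, of which 4638 (25.9%) lay at or before the last listed rank. A gene missing from the table can have failed on fold change or on q-value, so no statement is made about the direction of genes that were not listed. The listed genes were chosen by the authors from these libraries, so tests on them here are not independent evidence.

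The value of each listed gene was transformed to log2(value + 1) and tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend and robust estimation), knockout minus control, with no covariates and a two-sided test. Benjamini-Hochberg adjustment took all 17910 genes as tested and ranked the listed genes alone, as if genes not listed had larger p-values, and the threshold was 0.05. That does not hold in the authors' test, where the last of the 778 listed genes stood at rank 4638, so many genes ahead of the weaker listed ones are missing from the table. A higher true rank gives a smaller adjusted p. For the p-values of this fit, the limma adjusted p-values over all genes tested are therefore upper bounds. A listed gene that did not pass could pass if all genes were ranked. The p-values themselves rest on variances estimated from the selected genes alone, and in a fit to all genes they could be larger or smaller. For low genes, log2 fold changes on this scale can lie below or above the authors'. That of Glycam1 was 6.05 against 7.16, and that of Cox6a2 4.83 against 4.55. Means ± SD are of normalised counts. A count-based test, its normalisation factors and filters, and competitive gene set tests had been chosen before the data were examined. They were not run, because the table held neither counts nor the unchanged genes. The comparison of rod with cone or inner retinal list scores was not run either, since Gnb3 was the sole cone gene listed and inner retinal markers were not listed.

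Simulated data were built from the 778 listed genes, with 200 of them changed in each of 20 runs. With adjustment over all tested genes, limma recovered 31.7% of changes of 1 on the log2 scale and 59.8% of changes of 2. Of the genes it called, 0.154% were unchanged ones, a share kept low because 778 genes were simulated and 17910 counted as tested. With adjustment over the listed genes alone it recovered 56.4% and 86.3%, and 3.13% of the genes it called were unchanged ones. The real listed genes had all been selected for differing between the groups, so these shares do not give the share of false calls among them.

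In place of the planned set tests, 30 gene lists fixed before the data were examined were tested for over-representation among the higher and among the lower listed genes, with 17910 genes as background (hypergeometric test, one-sided, 60 tests with Benjamini-Hochberg adjustment). The 30 lists covered retinal cell types, glial and immune responses, stress and mitochondrial pathways, and tissues next to the retina. A list of 5 sex-linked genes was only looked up, and 0 of them were listed. Members were counted when their symbol was in the gene name table or among the listed genes. The gene name table held 745 of the 778 listed symbols. Genes of a list are not independent, so these p-values are too small. In 2000 random 30-gene lists, 1.25% gave a p under 0.05 among the higher genes. Where at least 3 members were listed, a list score was taken as the mean log2(value + 1) of the listed members in each library, and groups were compared with an exact two-sided permutation test over 70 relabellings, whose smallest p is 0.0286. For the 7 lists other than lens this test gave that smallest p (adjusted p = 0.0327). It is void there, since the listed members had been selected for differing between the same groups in one direction, so their scores are given as values without a p.

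Named genes followed a rule set before the data were examined: Phb2, the 10 largest rises and 10 largest falls past the threshold with groups that did not overlap, and up to 4 listed members of each list with the smallest p. The rule's minimum of 1 CPM could not be computed and was replaced, after the values were seen, by a mean of at least 10 normalised counts. Other genes named were chosen after their values were seen. A further 7 lists were drawn up after the listed genes were seen. Neighbouring genes were taken from the RefSeq gene order of assembly GRCm38.p6, which is not the authors' build, so it served for names and order alone. Of the listed genes, 760 matched it. Alternatives were 2 other pseudocounts (0.5 and 10), a minimum mean of 10, no variance trend, adjustment over the listed genes alone, a test against a 1.5-fold change, leaving out each library in turn, and leaving out controls 3 and 4 together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.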

Results

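Retinal RNA was compared between 4 control and 4 rod_Phb2_KO libraries from mice that the series title gives as C57BL/6J. Phb2 encodes prohibitin 2, a protein of the inner mitochondrial membrane, and the comparison asks how its depletion in rod photoreceptors changed gene expression in the whole retina. The labels give no age, sex, litter or batch, and nothing says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. Library depth is unknown. The normalised counts of the 778 listed genes summed to between 3482565 and 3896562 in the controls and between 1826502 and 2109446 in the knockouts, and Rho alone made up 46.6% to 47.5% of that sum in the controls and 28.2% to 31.4% in the knockouts. Over the listed genes, Pearson's r of log2 values was 0.925 to 0.973 within groups and 0.81 to 0.888 between groups, and no pair of libraries held identical values. These correlations are across genes, which are not independent replicates and were selected for differing between the groups.

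Phb2 was lower in every knockout library, at 1548 ± 37.9 normalised counts (SD, n = 4) against 3208 ± 208 (SD, n = 4) in controls. The log2 fold change was -1.05 (SE 0.0869, limma adjusted p = 2.5e-06), a 2.07-fold lower mean. In the authors' deposited table the log2 fold change of Phb2 was -1.05. The labels restrict cre to rods and do not say which part of the gene was floxed, so reads from other retinal cells and from outside the removed part are included in this value.

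Among listed genes, those of rods fell, and most of those of the integrated stress response, reactive glia, microglia, complement and interferon signalling rose. Of the 778 listed genes, 586 were higher and 192 lower in the authors' deposited table, which is 3.27% and 1.07% of the genes tested. With limma, 398 were higher and 90 lower past the threshold over all genes tested. For the p-values of this fit the adjusted ones are upper bounds, because genes missing from the table could not be ranked. Of the listed genes, 655 had groups that did not overlap, including all 488 past the threshold. Chance gives 2.86% of unselected genes for 4 against 4, but these genes had been selected for differing between the groups, so their number is a description and not a test. Against a 1.5-fold change rather than 0, limma left 250 higher and 53 lower genes. Adjusted over the listed genes alone, it gave 580 higher and 174 lower.

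Of the 25 rod photoreceptor genes, 8 were listed and all 8 fell past the threshold (limma adjusted over all genes tested and also adjusted over the list alone), with log2 fold changes from -1.57 to -1.01. The list was over-represented among lower genes (hypergeometric adjusted p = 1.4e-09). Rho, the rod visual pigment opsin, fell from 1721242 ± 110602 to 582256 ± 67213 normalised counts (SD, n = 4 per group), with a log2 fold change of -1.57 (SE 0.0808, limma adjusted p = 2.2e-08). Gnat1, the rod transducin alpha subunit, had a log2 fold change of -1.23, Nrl, a transcription factor needed for rod identity, -1.42, and Slc24a1, the rod sodium/calcium-potassium exchanger, -1.09. At an absolute log2 fold change of at least 1.5 in the authors' deposited table, an alternative chosen after the values were seen, 1 rod gene was left and the list was not over-represented (adjusted p = 0.81). The mean log2 value of the 8 listed members was lower in the knockouts, with a difference of -1.28.

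**Figure D1:**
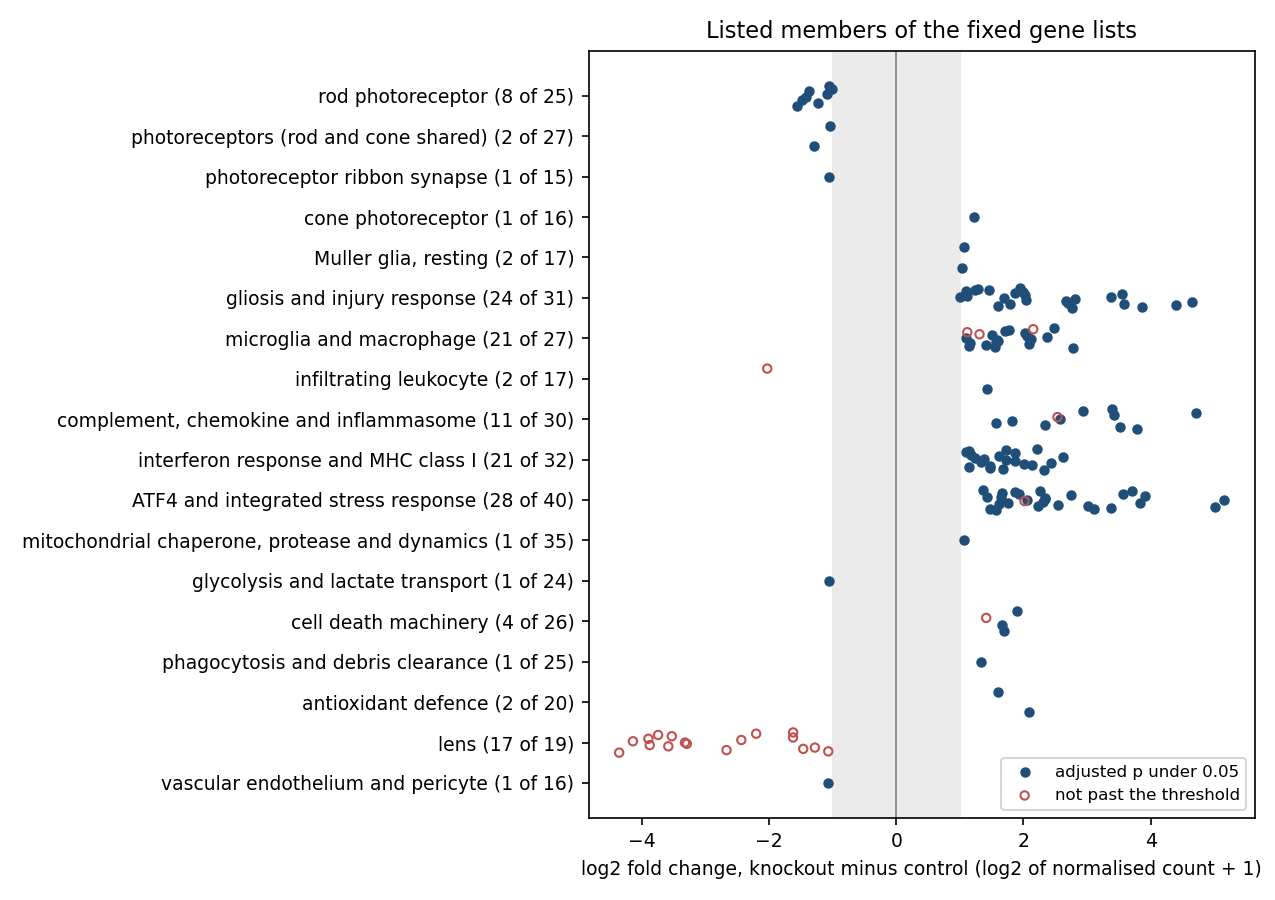
Log2 fold change (knockout minus control, log2 of normalised count + 1) of each listed member of the fixed gene lists, with the number listed out of the list's members in brackets. Filled points passed the limma threshold over all genes tested, open points did not, the shaded band marks log2 values from -1 to 1 and the vertical spread within a row has no meaning. The 8 rod genes lie at -1.01 or below, the 24 gliosis genes at 1.01 or above, and the 17 lens genes are all open.

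Other photoreceptor lists had few listed members. From the 27 genes shared by rods and cones, Prph2, a structural protein of outer segment discs, and Rdh12, a retinol dehydrogenase, fell with log2 fold changes of -1.29 and -1.04, and the list was not over-represented among lower genes (adjusted p = 0.22). Slc17a7, the vesicular glutamate transporter of photoreceptor terminals, was the sole listed gene of 15 in the ribbon synapse list and fell (log2 fold change -1.07, SE 0.0797). The list was not over-represented among lower genes (adjusted p = 0.72). Gnb3, the cone transducin beta subunit also used by ON bipolar cells, was the sole listed gene of the 16 cone genes. It rose from 17155 ± 822 to 40224 ± 3937 normalised counts (SD, n = 4 per group, log2 fold change 1.23), and the cone list was not over-represented among higher genes (adjusted p = 1.0). No gene of the bipolar (20 genes), amacrine (17), horizontal (8) or ganglion cell (15) lists was listed.

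Of 40 genes of the integrated stress response, driven by the transcription factor ATF4, 28 were listed, all as higher, and 27 passed the threshold (28 adjusted over the list alone), with a median log2 fold change of 2.28 among listed members. Mthfd2, a mitochondrial enzyme of one-carbon folate metabolism, rose from 252 ± 56.3 to 3564 ± 115 normalised counts (SD, n = 4 per group), with a log2 fold change of 3.84 (SE 0.14, limma adjusted p = 1.4e-09). Trib3, a pseudokinase induced by ATF4 and CHOP, rose 10.3-fold in mean. Slc7a1, a cationic amino acid transporter, and Aldh18a1, which starts proline synthesis, had log2 fold changes of 2.33 and 2.31. The member not past the threshold over all genes was Fgf21 (log2 fold change 2.02, limma adjusted p = 0.16). The list was over-represented among higher genes (adjusted p = 3.2e-31), and the mean log2 value of its listed members was higher in the knockouts by 2.57.

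Of 31 markers of Müller glial reaction and retinal injury, 24 were listed and all 24 rose past the threshold (24 adjusted over the list alone), with log2 fold changes from 1.01 to 4.65, and the list was over-represented among higher genes (adjusted p = 6.1e-29). Gfap, the intermediate filament of reactive glia, rose from 974 ± 145 to 6584 ± 315 normalised counts (SD, n = 4 per group), and Edn2, an endothelin made by stressed photoreceptors, from 306 ± 52.3 to 6534 ± 1454. Their log2 fold changes were 2.77 and 4.40. A2m, a protease inhibitor, had a log2 fold change of 3.37 and Stat3, the transcription factor downstream of interleukin-6 family cytokines, 1.78. The mean log2 value of the listed members was higher in the knockouts by 2.35. Among 17 genes of resting Müller glia, Clu and Crym were listed, and both rose (log2 fold changes 1.03 and 1.07). The list was not over-represented among higher genes (adjusted p = 0.63).

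**Figure D2:**
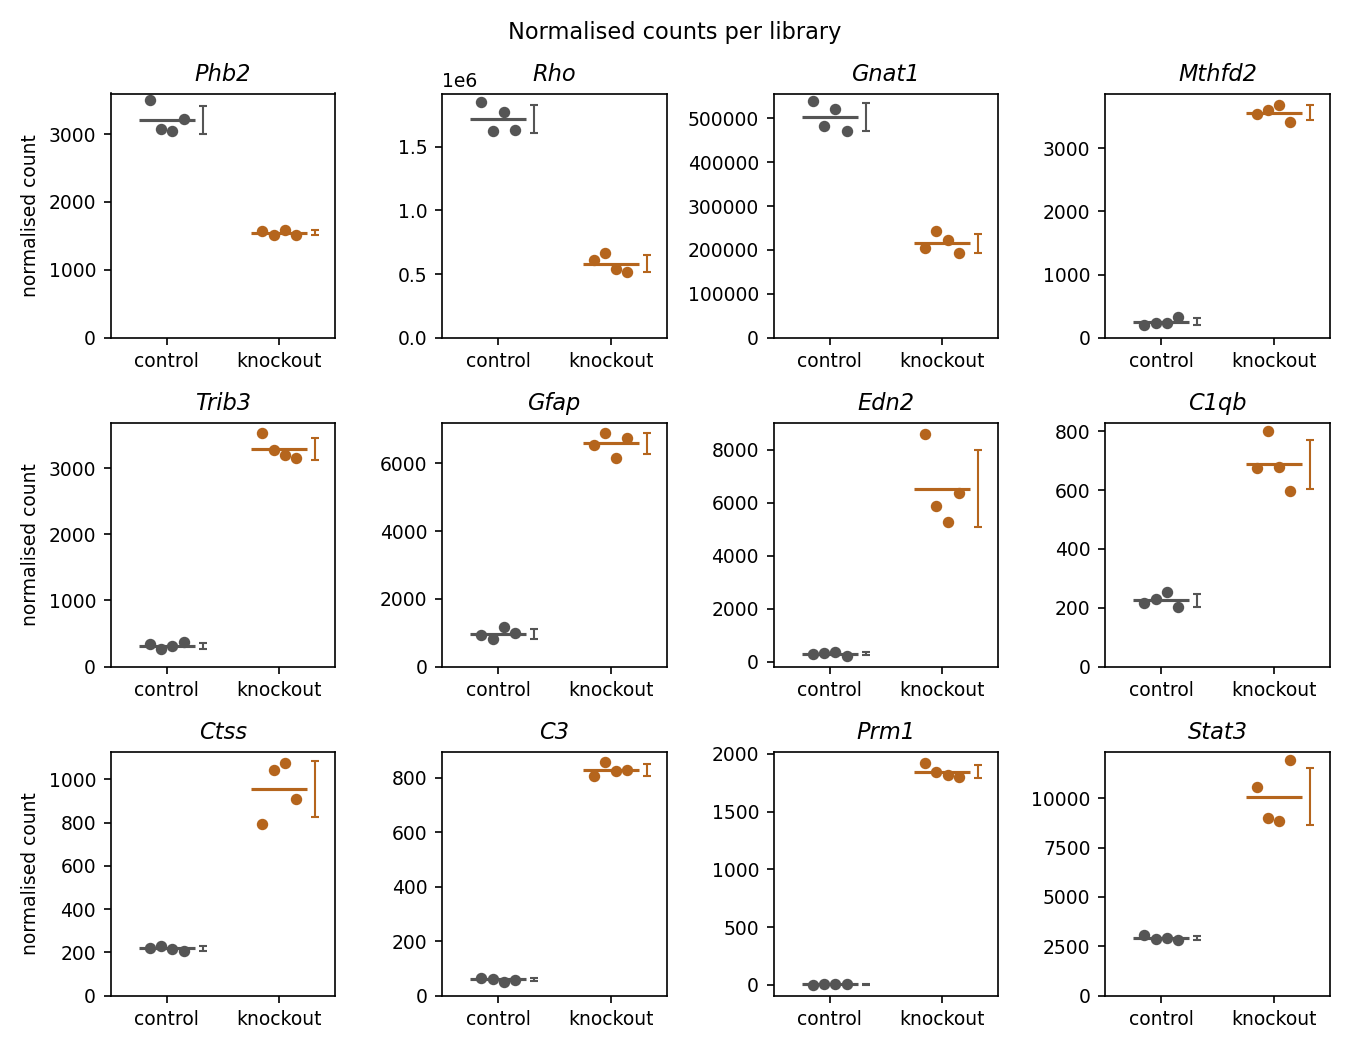
Normalised counts (linear axes) of 12 genes in the 4 control and 4 knockout libraries, with each point a library, horizontal lines the group means and vertical bars the mean ± SD. Groups do not overlap in any panel, and Phb2 lies at 1513 to 1584 in the knockouts and at 3044 to 3498 in the controls.

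Of 27 microglia and macrophage genes, 21 were listed, all as higher, and 18 passed the threshold (21 adjusted over the list alone), with log2 fold changes from 1.10 to 2.78 (list adjusted p = 1.7e-25 among higher genes). Ctss, the lysosomal protease cathepsin S, rose from 219 ± 10.7 to 955 ± 130 normalised counts (SD, n = 4 per group, log2 fold change 2.11). Csf1r, the receptor that maintains microglia, had a log2 fold change of 1.41, the integrin Itgam 2.08, and the complement component C1qb had a mean of 688 ± 83.7 against 225 ± 22.0 (SD, n = 4 per group). The members not past the threshold over all genes were Cd53, Fcer1g and Cst7, with log2 fold changes of 1.31, 1.12 and 2.15. The microglial score was 5.71 ± 0.0165 in controls and 7.45 ± 0.162 in knockouts (SD, n = 4 per group). Of 17 leukocyte genes, Ptprc, the CD45 antigen that microglia also carry, rose (log2 fold change 1.43). The B cell gene Cd79a was listed as lower and did not pass the threshold (log2 fold change -2.03, limma adjusted p = 0.18, and 0.0499 without knockout 3). This list was not over-represented among higher or lower genes (adjusted p = 1.0 and 0.72).

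Of 30 complement, chemokine and inflammasome genes, 11 were listed, all as higher, and 10 passed the threshold (11 adjusted over the list alone), with a median log2 fold change of 2.94 and list adjusted p = 1.1e-08. C3, the central complement component, rose from 59.5 ± 6.25 to 829 ± 20.9 normalised counts (SD, n = 4 per group, log2 fold change 3.78). C4b had a log2 fold change of 3.52, Serping1, the C1 inhibitor, 2.57 and the pattern receptor Tlr2 3.39, although C4b has a near-identical copy, C4a, with which reads can be shared. Ccl2 did not pass the threshold over all genes (log2 fold change 2.54). The mean log2 value of its listed members was higher in the knockouts by 2.96.

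Of 32 interferon-induced and class I antigen presentation genes, 21 were listed and all 21 rose past the threshold (21 adjusted over the list alone), with a median log2 fold change of 1.68 and list adjusted p = 5.0e-23. B2m, the light chain of class I molecules, rose from 470 ± 115 to 1710 ± 316 normalised counts (SD, n = 4 per group, log2 fold change 1.87), Ifitm3 by 1.72, the transcription factor Irf1 by 1.47 and H2-D1, a class I heavy chain with close paralogs, by 1.15 on the log2 scale. The score was 6.90, 6.84, 7.55 and 7.77 in controls 1 to 4 and 8.91 to 9.10 in the knockouts, a difference of 1.70. Without controls 3 and 4, a choice made after the values were seen, all 21 listed interferon genes passed the limma threshold and the difference was 2.09. Of all listed genes, 452 passed. Controls 3 and 4 had the highest interferon scores of the controls. Leaving them out therefore had to widen the difference, and it does not test how stable the interferon result was.

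The fixed list of cell death genes gave few calls. It did not hold every such gene: Bik, a BH3-only gene outside it, had a log2 fold change of 3.72 in the authors' deposited table. Of 26 genes, Cdkn1a, Bbc3 and Hrk rose past the threshold (log2 fold changes 1.89, 1.69 and 1.67), which encode a cell cycle inhibitor and 2 BH3-only proteins. Fas was listed as higher and did not pass over all genes (log2 fold change 1.41, limma adjusted p = 0.088), whereas all 4 passed adjusted over the list alone. The list was not over-represented among higher genes (adjusted p = 0.072, and from 0.037 without genes averaging under 10 normalised counts to 0.65 with a smaller background).

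Few genes of the mitochondrial and metabolic lists were listed. Hspa9, the chaperone mortalin of the mitochondrial matrix, was the sole listed gene of 35 in the chaperone, protease and dynamics list and rose from 4646 ± 467 to 9678 ± 633 normalised counts (SD, n = 4 per group, log2 fold change 1.06). No gene was listed from the list of 76 nuclear-encoded subunits of oxidative phosphorylation, the 13 mitochondrially encoded protein genes, the 20 genes of the TCA cycle or the 23 of cholesterol synthesis. The list of 76 did not hold every such subunit. Cox6a2, a subunit gene of cytochrome c oxidase outside it, was listed and rose (log2 fold change 4.83, limma adjusted p = 0.00028). Slc16a3, a lactate transporter, was the sole listed gene of 24 in the glycolysis list and fell (log2 fold change -1.06). Hmox1, heme oxygenase 1, and Osgin1 rose among 20 antioxidant genes, Hmox1 with a log2 fold change of 2.09 and Osgin1 from 37.8 ± 21.0 to 108 ± 22.4 normalised counts (SD, n = 4 per group), and Pros1, a ligand of phagocytic receptors, among 25 phagocytosis genes (log2 fold change 1.33). None of these lists was over-represented in the direction of its listed members, with adjusted p from 0.72 to 1.0. The limma call of Osgin1 was lost without knockout 3 (adjusted p = 0.061) and without control 1 (adjusted p = 0.052).

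Lens genes were listed as lower and varied widely among the control libraries. Of 19 lens genes, 17 were listed, all as lower, and the list was over-represented among lower genes (adjusted p = 8.0e-31), yet 0 passed the limma threshold over all genes tested, 4 passed adjusted over the list alone and 5 had an unadjusted p under 0.05. The count of 0 depends in part on an adjustment that could not rank genes missing from the table, so it does not show that lens genes did not differ. Counting genes past that threshold only, the list was not over-represented (adjusted p = 1.0). Cryaa, alpha A crystallin, was at 940, 2020, 11750 and 2.95 normalised counts in controls 1 to 4 and between 0.544 and 134 in the knockouts. Lgsn, Bfsp1, Cryge and Lim2 had log2 fold changes of -1.62, -1.46, -4.14 and -2.67, with limma adjusted p from 0.12 to 0.21. The lens score was 6.50, 7.21, 9.07 and 2.37 in the controls and 2.18 to 4.49 in the knockouts, a difference of -2.83 (exact permutation p = 0.114, adjusted p = 0.114, n = 4 per group). Leaving out single libraries moved the difference from -4.14 without control 4 to -1.91 without control 3, with exact permutation p of up to 0.257. The limma adjusted p of Lgsn, Bfsp1 and Cryge was 0.023, 0.0085 and 5.1e-05 without control 4, and without other single libraries reached 0.41, 0.596 and 0.69, and that of Lim2 0.6997. The log2 fold change of Cryge ranged from -5.54 without control 4 to -3.53 without control 3. Gamma crystallin genes are close paralogs, so their separate values are uncertain.

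**Figure D3:**
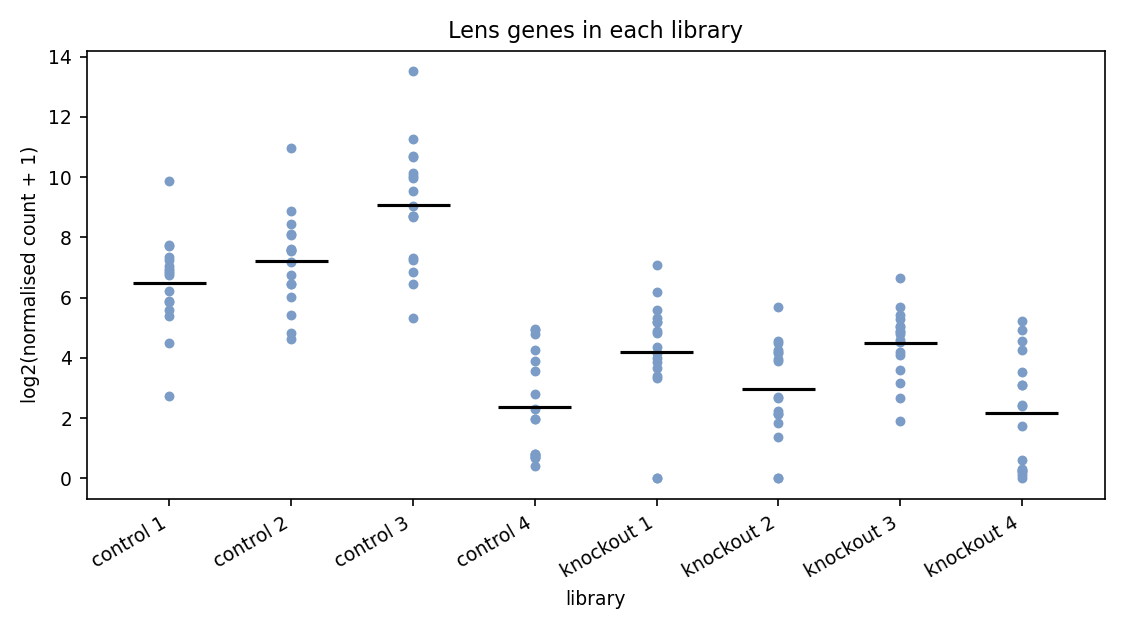
Log2(normalised count + 1) of the 17 listed lens genes in each of the 8 libraries, with each point a gene and each black line the mean of a library. The mean is 9.07 in control 3 and 2.37 in control 4, and 2.18 to 4.49 in the knockouts.

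Of the markers of other neighbouring tissues, few were listed, which does not give their level in the libraries. No gene of the retinal pigment epithelium (15 genes), red blood cell (6), oligodendrocyte (8) or extraocular muscle (10) lists was listed. Vtn, which encodes vitronectin, was the sole listed gene of 16 in the vascular list and fell (log2 fold change -1.07, SE 0.0795), and that list was not over-represented among lower genes (adjusted p = 0.72). Its fall lay within the range of the listed rod genes (-1.57 to -1.01). Bulk RNA does not show which cells it came from, so it cannot be read as a vascular change.

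On the log2(value + 1) scale, the largest rises were led by Prm1, which encodes a sperm chromatin protein. In the authors' deposited table the log2 fold change of Fut1 was larger than that of Prm1. Prm1 was at 1847 ± 54.9 normalised counts in knockouts and 2.92 ± 1.48 in controls (SD, n = 4 per group), with a log2 fold change of 8.97 (SE 0.275, limma adjusted p = 7.2e-10). Fut1, a fucosyltransferase gene, was listed at 0 in every control library and at 110, 78.8, 99.8 and 76.9 normalised counts in knockouts 1 to 4, so no fold is given. Such zeros and near-0 values cannot be read as absence: 36 genes were at exactly 0 in all 4 controls, while values above 0 and below 0.5 numbered 42 to 49 in each control, 24 in knockout 4 and 0 in the other knockouts, so low values did not arise alike in all libraries. Glycam1 was at 94.2 ± 43.0 in knockouts and at 2.06 or less in each control. Gdf15, a secreted stress cytokine, and Chac1, a glutathione-degrading enzyme, both in the ATF4 list, had log2 fold changes of 5.16 and 5.02. In the controls, Chac1 was at 65.4, 87.3, 89.8 and 321 normalised counts. The others were Cox6a2, Cxcl10, Bcl3, Lad1 and the unnamed gene model C430049E01Rik, with log2 fold changes from 4.49 to 4.83.

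Among the largest falls past the threshold, Prss56, a serine protease gene, fell from 544 ± 93.2 to 60.7 ± 27.0 normalised counts (SD, n = 4 per group, log2 fold change -3.27, limma adjusted p = 5.5e-05). Glb1l3 and Hdc, the histamine-producing histidine decarboxylase, had log2 fold changes of -3.03 and -2.77. Ccdc24, Knstrn, Gdf5 and Pifo lay between -2.24 and -2.12, and the unnamed gene models 2610528A11Rik, Gm41793 and Gm7616 between -2.37 and -1.90. Leaving out single libraries ended some of these calls. That of 2610528A11Rik was lost without knockout 1, 2 or 3 or control 2, 3 or 4 (limma adjusted p of up to 0.121), that of Pifo without knockout 1, 3 or 4 or control 1, 2 or 4 (up to 0.0881), and that of Gm41793 without knockout 1 or 4 or control 1, 2 or 4 (up to 0.121). That of Gdf5 was lost without control 1 (adjusted p = 0.051).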

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

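The named genes and list scores were searched for a library standing apart within its group of 4. The measure was the gap to the nearest library as a share of the group's range. Gap and range were taken on the log2 scale of the limma fit, although gene values below are given as normalised counts. In 12 of the 150 groups this share was above Dixon's critical value, where chance gives about 7.5. The search itself was planned, and all tests of explanations below were chosen after the results were seen.

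Control 4 stood apart 4 times. Its Prss56 value was 405 normalised counts against 578 to 600.1 in the other controls (gap 0.905 of the range), its Glycam1 value 2.06 against 0.0168 or less (0.99), its Lgsn value 13.9 against 38.8 to 41.8 (0.932) and its Cryge value 0.343 against 46.8 to 86.6 (0.855). Control 1 was lowest for Cdkn1a (217 against 287 to 293, gap 0.928) and Hmox1 (93.1 against 138 to 142, gap 0.92) and highest for Hrk (99.3 against 59.0 to 64.0, gap 0.845). Control 3 was highest for A2m (273 against 197 to 205, gap 0.873). Among the knockouts, knockout 4 was lowest for Slc17a7 (61627 against 73610 to 74711, gap 0.923). Knockout 3 stood out for Cryge (2.75 against 0.0107 or less, gap 0.992) and for the interferon score (9.10 against 8.91 to 8.94, gap 0.844), and knockout 1 for Lim2 (listed at 0 against 3.73 to 5.33, gap 0.842). Low values did not arise alike in all libraries, since knockouts 1 to 3 held 0 values between 0 and 0.5 and each control 42 or more, which limits the reading of Glycam1, Cryge and Lim2.

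Lens genes made up 4 of these 12 results. Of the 17 listed lens genes, 16 had their highest value in control 3, and the median lens gene was 7.85 log2 units higher in control 3 than in control 4, so lens tissue carried over into some control libraries at dissection is a candidate explanation. An effect of the genotype in every library is argued against as the whole cause by the groups, which did not overlap for 1 of the 17 genes, and by control 4, which lay below the highest knockout for 16 of them. A smaller genotype effect beside carry-over stays open, as does expression by retinal cells, since 6 of the 17 genes were above 1 normalised count in every library and some crystallins are also made in retina. The labels say nothing of dissection.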

How the results depend on the processing

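No paired analysis was possible because the columns carry a group and no number that the labels tie to a sample of the other group. Alternatives other than the 1.5-fold test and leaving out single libraries were chosen after seeing the data. Genes past the limma threshold numbered 488, and 754 when adjusted over the listed genes alone (174 of them lower), because fewer genes were then counted as tested. Adjustment over all genes gives upper bounds for the p-values of this fit only. The 1.5-fold test left 303 (250 higher, 53 lower), as it asks for a larger change. Leaving out each library in turn gave 427 to 476 genes (341 to 391 higher, 79 to 90 lower) and a Phb2 log2 fold change from -1.07 to -1.01, and other pseudocounts, a minimum mean of 10, no variance trend and dropping controls 3 and 4 gave 444 to 510 genes. Of the lists, 2 were over-represented among lower genes, and 1 when only genes past the limma threshold counted (rod, since 0 lens genes passed) or only genes with an absolute authors' log2 fold change of at least 1.5 (lens, since Rho alone of the listed rod genes reached it). Over 990 comparisons of 66 named genes with these settings, 944 kept their side of the threshold, 34 no longer passed (7 genes), 12 newly passed (6 genes) and 0 reversed. List scores hold members selected in one direction, so their stability is not informative. Count-based tests and their normalisations, surrogate variables, competitive set tests and the rod against cone score were not run, since the values are not counts and unchanged genes are not in the table used here. Depth is unknown, so what it limits could not be assessed.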

Other observations

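All tests in this part were chosen after the results were seen, and the gene groups in its opening paragraphs were drawn up after the listed genes were known, so their counts describe the table and are not evidence of enrichment.

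Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 7 were listed (Aars, Cars, Gars, Iars, Mars, Tars and Yars), and all 7 rose past the limma threshold, with a median log2 fold change of 1.49. Aars rose from 7972 ± 297 to 25544 ± 491 normalised counts (SD, n = 4 per group), and Gars from 3043 ± 176 to 11076 ± 447. Cars and Gars were also in the ATF4 list. Of 17 genes drawn up as mitochondrial synthetases, 0 were listed. Gars, which serves both compartments, was counted as cytosolic, so the 2 groups are not a clean contrast.

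Of 30 cell cycle genes, 12 were listed, 11 as higher and Cenpa as lower, and 5 passed the limma threshold over all genes (Mki67, Aurkb, E2f8 and Kif14 as higher and Cenpa as lower). Mki67, the proliferation antigen, was at 37.3 ± 14.4 normalised counts in knockouts and 2.10 ± 2.89 in controls (SD, n = 4 per group). Immune receptor and effector groups were listed as higher: 5 of 6 phagocyte NADPH oxidase genes (3 past the threshold), 5 of 12 Toll-like receptors (3 past), 10 of 16 interferon-inducible GTPases (8 past) and 7 of 7 Fc receptors (3 past). Gbp2, an interferon-inducible GTPase with close paralogs, rose from 65.9 ± 30.2 to 390 ± 90.0 (SD, n = 4 per group).

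Prm1 was at 1799 or more normalised counts in each knockout library and at 4.16 or less in each control. A candidate explanation is Prm1 sequence carried by the cre transgene, since some cre constructs end in the untranslated region of a protamine gene, but the labels do not describe the construct and the table cannot place reads within the gene. Activation of a spermatid gene programme is the other explanation weighed, and 0 of 12 other spermatid genes looked up were listed. For those of the 12 that were tested, this argues against a rise near that of Prm1. Smaller rises stay open because genes below the authors' limits are left out. The transgene and the genotype cannot be told apart here, because cre was present in knockouts alone.

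Several explanations were weighed for the lower rod genes and the higher stress, glial, microglial and interferon genes. In the normalised values, a shift of more than 2-fold common to all genes outside rods, from rod loss or from scaling, is argued against. Of all tested genes, 3.27% were listed as higher, although those outside rods were not counted apart. Of the 4638 genes at or before the last listed rank, 778 were listed. No gene of the bipolar (20 genes), amacrine (17), horizontal (8) or ganglion cell (15) lists was listed. This takes the genes missing at those ranks to have failed on fold change. Before scaling, such a shift could not be tested. The scaling of the values is not given, and one that centres the typical gene near no change would hide such a shift. A smaller common shift stays open as well. An equal loss of every rod transcript, as from fewer rods, is argued against as the whole cause. The 8 listed rod genes did not keep their ratios to each other between the groups. The deviation from the rod mean on the log2 scale was -0.29 for Rho and 0.27 for Esrrb, and 7 of the 8 deviated without overlap. That mean is of the same 8 genes, so deviations of some shift the others the opposite way. The 7 are therefore not separate results. The 8 genes had also been selected for their fall, so no chance share is set against this count. Rod loss joined by a change within rods, or by expression of some members in other cells, stays open. An equal gain of microglia, with no change within them, could neither be excluded nor supported, as 4 of the 21 listed microglial genes deviated from their mean without overlap.

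Among the 575 higher genes placed in the RefSeq order of protein-coding genes, 30 neighbouring pairs were found outside gene families (names that differ in their first 3 letters), against a mean of 12.3, a 95th percentile of 18 and a maximum of 26 in 10000 random sets of the same size drawn from all 21900 protein-coding genes, expressed or not. The rule let through at least 4 pairs of related genes (Mt1 and Mt2, Igtp and Irgm2, C1ra and C1s1, and F830016B08Rik and Iigp1), and without them 26 pairs were left, above the 95th percentile and equal to the maximum of the random sets. In that assembly 8 of the 30 pairs overlapped. The pairs included Fgf21 and Fut1, Ddit3 and Mars, Lad1 and Tnnt2, and Fgf2 and Nudt6, whose log2 fold changes were 3.59 and 2.80. Near Phb2, 5 genes listed as higher lay within 10 genes on either side, a window chosen after the results were seen. They were C1rl, C1ra and C1s1, neighbouring complement proteases of one family, Spsb2, and Gnb3 at the edge of the window.

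The 4 against 4 grouping gave 488 genes past the limma threshold, and 1 of the 35 splits of the 8 libraries, the real one, gave as many, with 7 genes in the highest other split. Because the authors had selected the listed genes by the real grouping, this count does not test whether chance can be excluded.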
